A study of Homo sapiens with 6 samples.

How the data were processed

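Gene expression was measured by RNA sequencing of total RNA from KYSE150 cells, with 3 TPA and 3 DMSO libraries. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with standard Illumina methods. The deposited table holds raw counts of reads per gene symbol, 1 column per library, with no normalization. Per the submitters' processing notes, HISAT2 2.1.0 (an aligner) and HTSeq 0.12.4 (a read counter) were used with builds named hg38 and GRCh38. The annotation release, the strand setting and the read layout are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies may share or lose reads. Of the table's columns 0 fell outside the labels, and 0 of its 60591 rows named no gene. Columns named control were matched to the DMSO samples of the same number.

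Library totals ran from 27702329 to 33965547 counts, so a count of 0 in a library allowed up to 0.0915 to 0.109 CPM (3 counts over the TMM-scaled size). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Ratios of genes with 1 to 3 counts in a group have exact 95% binomial intervals over summed counts. CPM values are the deposited counts divided by the TMM-scaled library size, in the usual CPM unit.

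TPA was compared with DMSO by edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr and the group as the only term, and Benjamini-Hochberg adjustment at 0.05. This left 21825 genes. Standard errors of log2 fold changes are the estimate divided by the square root of F. The 22 gene lists, 17 of responses and 5 of checks, hold 569 distinct genes, of which 464 were tested and 2 stand in more than 1 list. The lists were written before the data were examined, as were the design, most alternatives and the rule for named genes. Lists with at least 5 tested members (19) were tested with limma's camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, with p adjusted over those lists. No list call of camera held with an estimated correlation, and other splits of the 6 libraries into 3 and 3 called 5 to 11 lists. The list of mitochondrially encoded genes had 0 tested members.

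The rule named the 6 genes with the largest rise and the 6 with the largest fall among genes that passed, had an average log2 CPM of at least 1 and had non-overlapping groups, leaving out clone and locus names, the 2 members of each response list with the lowest adjusted p, and PRKCA, PRKCD, PRKCE and PRKCH. Values of some genes that the rule takes are not reported here. List members named beyond this rule were chosen after their values were seen. The TPA and DMSO libraries share numbers 1 to 3 in their titles. Because the deviations of same-numbered libraries from their group means correlated above 0.1 in every pair (0.55, 0.34 and 0.37), the numbers were taken to pair the libraries, from the data and not from a stated shared culture or day. The correlation of DMSO 3 with TPA 2 (0.374) and of DMSO 2 with TPA 3 (0.356) was as high, so these correlations do not tell pairs 2 and 3 apart.

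Transcript GC content and length, gene type and gene coordinates (whole gene, from 1) came from GENCODE 29 on GRCh38. Of 60591 symbols 37725 matched by current symbol and 18800 by the symbol of that release, while 4066 matched none or more than 1, and 21024 of the tested genes (96.3%) had a GC value. The GC correction fitted each library's deviation of log2 CPM (prior count 2) from the mean of all libraries by a robust natural spline with 5 degrees of freedom on genes with an average log2 CPM over 2, and used the fitted trend as an offset.

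Alternatives planned beforehand were RLE factors, upper-quartile factors, library size only, no filter, a filter of at least 1 CPM in every library of a group and a total of at least 60 counts, DESeq2 1.42.0, limma-voom, the replicate block, each library left out in turn, camera with an estimated correlation, the fry rotation test, glmTreat at 2-fold and a threshold of 0.01. Alternatives added after seeing the data were a term for libraries numbered 1 against 2 and 3, both libraries numbered 1 left out, the GC correction with and without the block, the genes with a GC value only, and the block with an estimated correlation.

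The steps were tested on simulated counts drawn from the means, spread and library sizes of the TPA and DMSO libraries, with 200 genes changed. With the spread of the unblocked fit (21133 genes), 2.99%, 52.2% and 97.0% of genes changed 2-, 4- and 8-fold were recovered and 4.72% of 106 calls were not changed genes. With that of the blocked fit (21250 genes), 34.3%, 97.0% and 100% were recovered and 9.41% of 170 calls were not changed genes. Those counts held no difference between library numbers, so these rates do not describe the block on libraries that differ by number. With GC trends added (20550 genes), 18.7% of 171 calls of the blocked fit were not changed genes without the GC correction and 7.27% of 165 with it. The added trends had the form of spline that the correction fits, so a gain was built in. They were added as library differences, so the run does not show how the correction treats a TPA effect that follows GC content. Of 20 simulated lists, the 1 that was raised was called and 0 of the others. Genes were drawn independently in these counts, so the run does not show how the list test behaves where genes vary together.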

Results

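KYSE150 is an established human cell line from an oesophageal squamous cell carcinoma. TPA is a phorbol ester, a plant-derived compound that binds the diacylglycerol site of protein kinase C and activates it. The study compared gene expression in KYSE150 cells given TPA with that in cells given the solvent DMSO, with 3 libraries in each group. TPA was used at 10 ng/ml for 24 h on cells kept overnight without serum, per the labels, which state no dose or time for DMSO. The deposited values are raw read counts for 60591 genes. DMSO libraries 1, 2 and 3 held 28219863, 30207144 and 27702329 counts, and TPA libraries 1, 2 and 3 held 28915283, 33458280 and 33965547. Between 31487 and 33754 genes had a count in a library, and the 10 largest genes took 4.78% to 6.24% of the counts. The 13 mitochondrially encoded genes were listed at 0 in every library.

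The 6 libraries did not separate by treatment alone. The first principal component of log2 CPM (depth-scaled read counts) held 57.3% of the variance and set TPA 2 and TPA 3 apart from the other 4 libraries. The second component held 31.8% and set TPA 1 apart from DMSO 2 and DMSO 3, with DMSO 1 between them. Across genes, log2 CPM of TPA 1 correlated with that of DMSO 1 at r = 0.974, above its 0.927 with TPA 2 and 0.936 with TPA 3. TPA 2 with TPA 3 (r = 0.992) and DMSO 2 with DMSO 3 (r = 0.993) were the closest pairs, although their counts still differed by more than sampling noise (chi-square per degree of freedom 6.17 and 7.33). In the other pairs of libraries of 1 group this ratio ran from 47.9 to 262. Libraries with the same number deviated from their group means together, with correlations across genes of 0.55, 0.34 and 0.37 for numbers 1, 2 and 3. DMSO 2 with TPA 3 (0.356) and DMSO 3 with TPA 2 (0.374) were as high. Deviations from a mean of 3 libraries sum to 0, so these values set number 1 apart but do not pair numbers 2 and 3 singly. Results are therefore also given from a fit with the replicate number as a block wherever that changed a call or moved a count by over 1.5 times. Part of the spread of any fit with this block is the difference between numbers 2 and 3, which are close and may be technical replicates. P-values of such fits may therefore be too small. Genes are not independent replicates, so the correlations above carry no p-value.

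**Figure D1:**
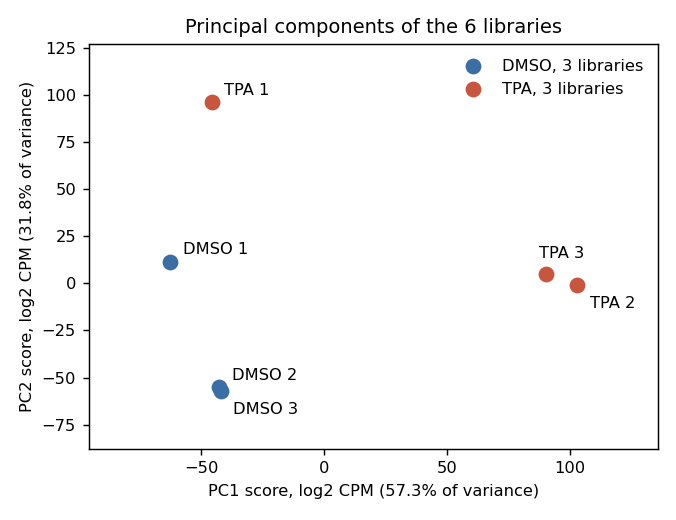
Scores of the 6 libraries on the first and second principal components of log2 CPM (x axis, 57.3% of the variance; y axis, 31.8%), 1 point per library, DMSO in blue and TPA in red. TPA 2 and TPA 3 lie apart from the other 4 libraries on the x axis, and DMSO 2 and DMSO 3 lie almost on each other.

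The size of the TPA against DMSO ratio also followed the GC content of the transcripts in pairs 2 and 3 but hardly in pair 1, where a pair is the TPA and DMSO library of 1 number. Over 12004 expressed genes, the mean log2 ratio of pairs 2 and 3 had a Spearman correlation of 0.65 with GC content, and the median ratio ran from -0.92 in the tenth of genes with the lowest GC content to 0.56 in the tenth with the highest. In pair 1 the correlation was -0.11 and those medians were 0.11 and -0.05. Response lists below are therefore also given from a fit that removes each library's trend on GC content and keeps the block, called the GC-corrected blocked fit, which was chosen after the trend was seen.

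**Figure D2:**
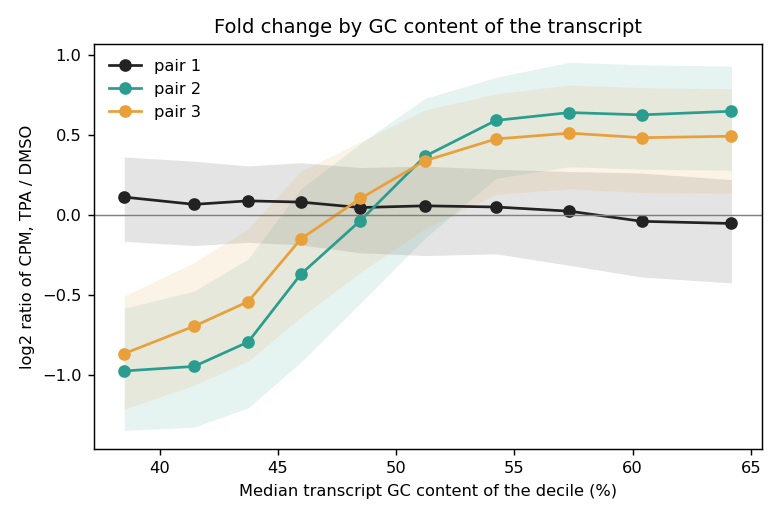
Median log2 ratio of CPM, TPA over DMSO (y axis), in equal bins of 12004 genes ordered by transcript GC content (x axis, median GC content in percent), for each pair of libraries with the same number. Lines join medians and shaded bands span the middle 50% of genes; pairs 2 and 3 run from below 0 at low GC content to above 0 at high GC content, and pair 1 stays between 0.11 and -0.05 at its ends.

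The comparison asked which transcripts differ between cells given TPA and cells given DMSO. Among genes that passed the test, had an average log2 CPM of at least 1 and had no overlap between the groups, the 6 largest rises included cytokine and receptor genes, and 3 of the 6 largest falls were interferon-stimulated genes. CCL3, a chemokine gene (chromosome 17, 36088256 to 36090169), rose from 0.282 ± 0.269 CPM in DMSO to 136 ± 17.1 CPM in TPA (SD, n = 3 each), a log2 fold change of 8.91 ± 0.63 (SE). CSF2, which encodes the cytokine GM-CSF (chromosome 5, 132073790 to 132076170), rose from 0.389 ± 0.47 to 79.1 ± 33.6 CPM (log2 7.66 ± 0.92). IL1R2, a decoy receptor for interleukin 1 (chromosome 2, 101991844 to 102028544), rose by log2 7.34 ± 0.83 to 51.0 ± 0.793 CPM. SERPINB2, an inhibitor of urokinase (chromosome 18, 63871692 to 63903890), rose by log2 7.26 ± 0.87 to 346 ± 240 CPM. VAV3, a guanine nucleotide exchange factor gene (chromosome 1, 107571160 to 107965144), fell from 31.1 ± 16.2 to 3.23 ± 0.929 CPM, a log2 fold change of -3.26 ± 0.50.

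The 2 other genes among the 6 largest rises had almost no counts in DMSO. ZP4, an egg coat glycoprotein gene (chromosome 1, 237877864 to 237890922), had 2 counts in DMSO and 869 in TPA, a ratio of 463 (95% counting interval 128 to 3832). IL13RA2, an interleukin receptor gene (chromosome X, 115003975 to 115019977), had 1 and 412 counts, a ratio of 439 (78.4 to 17395). These intervals cover counting error only. The other large falls were SERPINB13, a serpin of squamous epithelia (chromosome 18, 63586989 to 63604639; log2 -3.09 ± 0.54), the interferon-stimulated genes IFIT3 (chromosome 10, 89327894 to 89340971; -2.86 ± 0.48), DDX60 (chromosome 4, 168216293 to 168318807; -2.78 ± 0.38) and RSAD2 (chromosome 2, 6865806 to 6898239; -2.77 ± 0.48), and the pseudogene IGFL1P1 (chromosome 19, 46196238 to 46197323; -2.60 ± 0.41). Adjusted p for these 12 genes lay between 0.0116 and 0.0487 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CCL3 and IGFL1P1 have near-identical copies, so reads may be split among them and their levels are uncertain. Without DMSO 1 the log2 fold changes of CCL3, CSF2, IL1R2 and SERPINB2 were 10.04, 9.26, 8.32 and 8.30, and without TPA 1 that of SERPINB2 was 6.64. The fitted values of ZP4 and IL13RA2, which depend on the prior count, were 11.27 and 10.20 without DMSO 1 and 7.80 and 7.25 without TPA 1. In the GC-corrected blocked fit SERPINB13 had -2.47 and DDX60 -2.12.

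**Figure D3:**
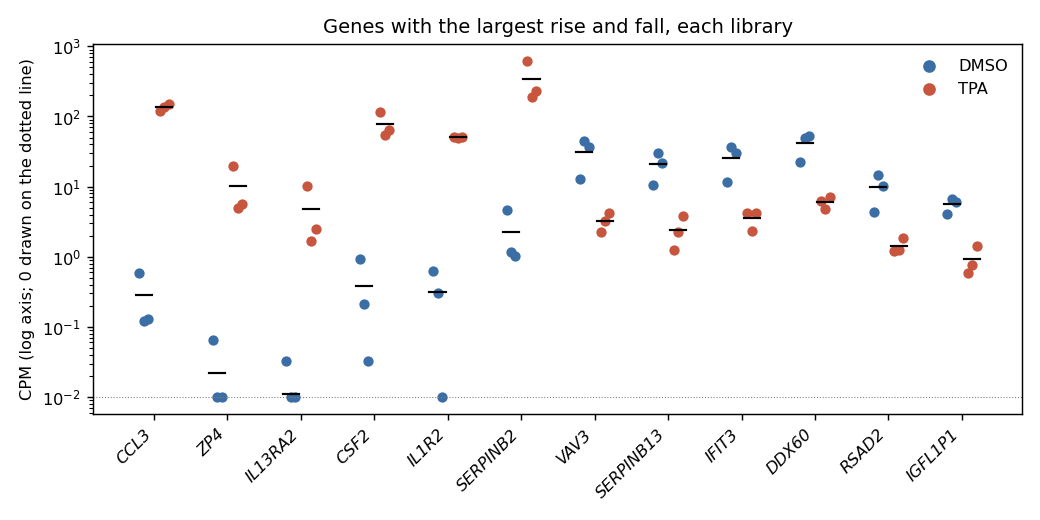
CPM in each library (y axis, log scale, a value of 0 drawn on the dotted line) of the 6 genes with the largest rise and the 6 with the largest fall among genes that passed, had an average log2 CPM of at least 1 and had no overlap between the groups, DMSO in blue and TPA in red, with the mean of 3 libraries as a black bar. CCL3 goes from a mean of 0.282 to 136 CPM and VAV3 from 31.1 to 3.23 CPM.

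Of 21825 genes tested, 188 were higher and 86 lower in TPA at an adjusted p under 0.05 (edgeR quasi-likelihood). All 274 had a fitted change of at least 2-fold and the same direction in all 3 pairs. Not all reached 2-fold in each pair (MAFG had log2 0.97 in pair 1). Passing at this spread favours both traits, so they are not separate support. At an unadjusted p under 0.05 there were 4814 genes. With the replicate block the counts were 1000 higher and 1423 lower, and the GC-corrected blocked fit called 1879 and 2127 of 21024 genes with a GC value. All 274 genes were called in the same direction with the block, and all 269 of them with a GC value in the GC-corrected blocked fit, while the GC correction without the block kept 225. These fits use the libraries from which the 274 were chosen, so their calls of the same genes are not separate support. Scaling by library size alone called 126 higher and 219 lower, 36.5% higher against 68.6% with the TMM factors used, and moved the median log2 fold change of all genes from -0.11 to -0.36. With DESeq2's median-ratio (RLE) factors that median was -0.01. Counts depended on each library: without DMSO 1 they were 101 and 38, without DMSO 2 and without DMSO 3 both were 0 (2612 and 2745 genes at an unadjusted p under 0.05), without TPA 1 5577 and 6297, without TPA 2 24 and 1, and without TPA 3 2 and 0. Leaving out both libraries numbered 1 gave 7216 higher and 7475 lower, from 2 close libraries against 2. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

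No gene in the list of phorbol ester receptors and the protein kinase C family passed in the comparison of 3 with 3 libraries. Of its 18 tested members 0 passed over all genes (edgeR) or adjusted over the list alone, with 7 at an unadjusted p under 0.05, 3 higher with DESeq2 and 0 with limma-voom. Without both libraries numbered 1, 9 were called higher and 7 lower. PRKCD had a log2 fold change of 0.92 ± 0.22 (adjusted p = 0.078) and DGKA, a diacylglycerol kinase gene, 0.85 ± 0.24 (0.104), and both passed with the replicate block (0.0417 and 0.0499), as did RASGRP1, lower (-1.45, 0.0256). PRKCA (-0.55 ± 0.23, adjusted p = 0.211), PRKCE (-0.34 ± 0.27, 0.500) and PRKCH (-0.10 ± 0.22, 0.816) did not pass, with or without the block. The list's median was 0.25, and 0.04 in the GC-corrected blocked fit, which called 2 higher and 1 lower, and camera did not call it (adjusted p = 0.225).

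Early-response genes that passed were mostly higher. In the list of AP-1 and immediate-early transcription factors, 4 of 23 tested members rose, 0 fell and 19 did not pass, and adjusted over the list alone 9 rose. IER3, a stress-induced survival gene, rose from 149 ± 35.8 to 618 ± 85.5 CPM (SD, n = 3; log2 2.05 ± 0.24, adjusted p = 0.0250), and the small MAF genes MAFG (1.35 ± 0.22, 0.0437) and MAFF (1.38 ± 0.24, 0.0487) and the AP-1 subunit gene JUNB (1.29 ± 0.23, 0.0498) rose too. FOSL1 (1.75 ± 0.39, 0.0681) and FOS (0.88 ± 0.25, 0.102) did not pass, but did with the block (0.00392 and 0.0466). The list's median log2 fold change was 0.67 and limma's camera test gave an adjusted p of 1.1e-07, against adjusted p = 0.268 with an estimated correlation. The block called 9 members higher and 0 lower, and the GC-corrected blocked fit 10 and 3, with a median of 0.46. With the GC correction and no block 2 were higher and 2 lower. Of 21 tested ERK pathway feedback genes, SPRY2, an inhibitor of receptor tyrosine kinase signalling, rose (1.25 ± 0.22, adjusted p = 0.0491) and IL1RAP fell (-1.90 ± 0.31, 0.0411), 19 did not pass, and adjusted over the list alone 7 rose and 1 fell. IL1RAP encodes the accessory chain of the interleukin 1 receptor and is not itself a feedback regulator. The list's median was 0.51 (camera adjusted p = 9.1e-05, adjusted p = 0.195 with an estimated correlation), the block called 7 higher and 1 lower, and the GC-corrected blocked fit 11 and 1, with a median of 0.46.

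Cytokine and NF-kB target genes had the highest median fold change of the lists tested. Of 29 tested members of that list 12 rose, 0 fell and 17 did not pass over all genes, 27 rose adjusted over the list alone, and the block called 26. IL24, an interleukin of the IL-10 family, rose from 2.09 ± 1.30 to 42.7 ± 10.5 CPM (log2 4.35 ± 0.48, adjusted p = 0.0250, and 5.0 without DMSO 1), beside CSF2. IL1B (2.63 ± 0.28), IL6 (2.41 ± 0.40) and the NF-kB inhibitor gene NFKBIA were also among the 12. The median log2 fold change was 1.99 (1.79, 2.23 and 2.11 in pairs 1, 2 and 3), and 2.38 in the GC-corrected blocked fit, which called 25 higher and 1 lower. Camera gave an adjusted p of 1.6e-22, and adjusted p = 0.146 with an estimated correlation.

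Among 28 tested secreted proteases and their inhibitors 6 rose, 0 fell and 22 did not pass, and adjusted over the list alone 11 rose and 1 fell. MMP9, a gelatinase gene, had 2 counts in DMSO and 185 in TPA, a ratio of 98.6 (95% counting interval 26.9 to 821; adjusted p = 0.0202). The other risers were SERPINB2, the collagenase gene MMP1 (2.31 ± 0.36), the urokinase gene PLAU (2.1 ± 0.27), its receptor gene PLAUR (2.55 ± 0.36) and ADAMTS1 (2.74 ± 0.44). The block called 11 higher and 2 lower. The list's median was 0.57, and 0.23 in the GC-corrected blocked fit, which called 11 higher and 3 lower (camera adjusted p = 2.9e-05, adjusted p = 0.195 with an estimated correlation). Of 9 tested EGF family ligands and receptors, TGFA rose (1.72 ± 0.23, adjusted p = 0.0312) and NRG1 fell from 204 ± 27.2 to 57.6 ± 3.27 CPM (-1.83 ± 0.21, 0.0250), and adjusted over the list alone 3 rose and 1 fell. The block added AREG and HBEGF as higher, and the list as a whole did not pass (camera adjusted p = 0.111). Its median was 0.46, and 0.08 in the GC-corrected blocked fit, which called 2 higher and 1 lower.

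A few squamous differentiation genes rose from very low levels. Of 22 tested members of the cornified envelope list 3 rose, 0 fell and 19 did not pass, and 7 rose adjusted over the list alone. SPRR2D, a cornified envelope precursor gene, had 0 counts in DMSO and 200 in TPA, at least 71.1-fold higher (floor of 3 counts over the group; adjusted p = 0.0296). SPRR2A also had no DMSO count, with 0.951 ± 0.423 CPM in TPA, and PI3, the gene of the protease inhibitor elafin, rose from 0.0735 ± 0.0452 to 1.16 ± 0.260 CPM (3.90 ± 0.52, 0.0304). SPRR2 genes are near-identical copies, so their counts are uncertain. The list's median was 0.50, the same with both SPRR2 genes at their bounds, but -0.34 in pair 1 against 0.84 and 0.70 in pairs 2 and 3. Camera gave an adjusted p of 0.0017, and adjusted p = 0.566 with an estimated correlation and 0.0606 with the stricter filter. The block called 7 higher and 1 lower (NOTCH3), and the GC-corrected blocked fit 7 and 4, with a median of 0.29.

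In the basal squamous list 2 of 21 tested members rose, 0 fell and 19 did not pass. Among them LAMB3, a laminin chain gene, rose from 576 ± 186 to 3818 ± 111 CPM (log2 2.73 ± 0.26, adjusted p = 0.0202). Adjusted over the list alone 4 rose and 2 fell. The block called 4 higher, adding LAMA3 and COL17A1, and 5 lower, namely KRT5, TP63, PDPN, NGFR and CAV1. KRT5, the basal keratin gene, had 1315 ± 768 CPM in DMSO and 355 ± 250 CPM in TPA, a log2 fold change of -1.89 ± 0.79 (adjusted p = 0.218, 0.00151 with the block). The list as a whole did not pass (camera adjusted p = 0.391, median 0.14), and in the GC-corrected blocked fit, with 3 higher and 6 lower, its median was -0.30. Among 32 tested junction genes CLDN1, a tight junction claudin gene, rose from 0.139 ± 0.116 to 7.08 ± 7.16 CPM (5.63 ± 0.97, adjusted p = 0.0487; 6.43 without DMSO 1 and 4.48 without TPA 1), 0 fell and 31 did not pass, and 5 rose adjusted over the list alone. CLDN4 (1.34 ± 0.27, 0.0626) did not pass, but did with the block (0.0204), which called 6 higher and 2 lower, the desmoglein genes DSG2 and DSG3. The junction list's median was 0.43, and 0.22 in the GC-corrected blocked fit, which called 7 higher and 3 lower (camera adjusted p = 0.0229, adjusted p = 0.290 with an estimated correlation and 0.0705 with the stricter filter).

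Mesenchymal genes went both ways. Of 22 tested, 3 rose, 2 fell and 17 did not pass. The fibronectin gene FN1 (2.1 ± 0.28) and its integrin receptor chain gene ITGA5 (1.92 ± 0.22) were among those that rose. TGFB2, a TGF-beta ligand gene, fell from 188 ± 37.7 to 31.6 ± 2.14 CPM (-2.57 ± 0.24, adjusted p = 0.0202, and -1.96 in the GC-corrected blocked fit), and the transcription factor gene SNAI2 fell (-1.42 ± 0.21, 0.0394). Adjusted over the list alone 6 rose and 4 fell, the block called 5 and 6, and the list did not pass as a whole (camera adjusted p = 0.506). Its median was 0.26, and -0.24 in the GC-corrected blocked fit, which called 7 higher and 7 lower.

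A few mitotic genes fell, and the shift of their list was not kept after the GC correction. Of 30 tested G2/M genes TOP2A, the DNA topoisomerase gene of dividing cells, fell from 218 ± 25.9 to 92.7 ± 6.74 CPM (-1.23 ± 0.20, adjusted p = 0.0411, and -0.64 in the GC-corrected blocked fit), and the spindle checkpoint gene BUB1B fell (-1.35 ± 0.24, 0.0498), 0 rose and 28 did not pass, with 11 lower adjusted over the list alone and 9 with the block. The median log2 fold change was -0.46 and camera gave an adjusted p of 0.00058, against adjusted p = 0.146 with an estimated correlation and 0.138 without TPA 1. These genes had a median GC content of 43.1%. The GC-corrected blocked fit gave a median of -0.18 and a camera adjusted p of 0.295, with 1 member higher and 5 lower. The pair medians were -0.68, -0.41 and -0.53 before the GC correction and -0.75, 0.14 and 0.02 after it. Of 34 tested G1/S and replication genes, CCNE1, the cyclin E1 gene, rose from 1.79 ± 0.0115 to 7.90 ± 1.39 CPM (2.14 ± 0.26, adjusted p = 0.0253), 0 fell and 33 did not pass, and adjusted over the list alone 1 rose and 3 fell. RFC3 had -1.08 ± 0.23 (0.0651, 0.0199 with the block, which called 4 lower). This list's median was 0.16, its mean -0.00 and its camera direction down (adjusted p = 0.713), but up without TPA 1 (0.0144), and with the GC correction and block the median was -0.12, with 1 higher and 4 lower. Its medians in pairs 1, 2 and 3 were -0.58, 0.42 and 0.29, so pair 1 went opposite to the others. Of 27 tested CDK inhibitor and p53 target genes, CDKN1A, which encodes the inhibitor p21, rose from 71.8 ± 16.4 to 377 ± 81.0 CPM (2.39 ± 0.27, adjusted p = 0.0250), 0 fell and 26 did not pass. CDKN2B had -1.27 ± 0.23 (0.0540, 0.0139 with the block). Adjusted over the list alone 5 rose and 2 fell, the block called 4 and 2, and the list did not pass (camera adjusted p = 0.526, direction up, with a median of -0.06 and a mean of 0.05), while the GC-corrected blocked fit gave a median of -0.11 with 7 higher and 5 lower.

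Cholesterol synthesis genes that passed were all lower. Of 23 tested members 4 fell, 0 rose and 19 did not pass, with 8 lower adjusted over the list alone, 12 with the block, 1 with the GC correction and no block and 19 in the GC-corrected blocked fit, and 0 higher in each of these. HMGCS1, which makes the HMG-CoA of the sterol pathway, fell from 405 ± 201 to 71.0 ± 7.19 CPM (-2.51 ± 0.42, adjusted p = 0.0445) and the sterol oxidase gene MSMO1 from 146 ± 58.4 to 30.3 ± 1.2 CPM (-2.26 ± 0.34, 0.0394). SC5D (-1.71 ± 0.31, 0.0498) also fell. In the GC-corrected blocked fit these 3 had smaller log2 fold changes, HMGCS1 -1.79, MSMO1 -1.58 and SC5D -1.12, and HMGCS1 and MSMO1 did not pass with the GC correction and no block. The median was -1.02 with and without the GC correction and block, and -1.03, -1.06 and -0.97 in pairs 1, 2 and 3. Camera gave an adjusted p of 9.1e-05, and adjusted p = 0.481 with an estimated correlation, 0.163 without TPA 1 and 0.125 with the fry test.

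More interferon-stimulated genes fell than rose. Of 30 tested, DDX60, IFIT3 and RSAD2 fell, ISG20, an exonuclease gene, rose (1.44 ± 0.26, adjusted p = 0.0498), and 26 did not pass. Adjusted over the list alone 2 rose and 8 fell, the block called 3 and 11, and the GC-corrected blocked fit 4 and 12. In pairs 1, 2 and 3 the list's medians were -0.22, -0.73 and -0.69. The median of the reported fit was -0.58, and -0.56 in the GC-corrected blocked fit (camera adjusted p = 0.0491 in the reported fit, adjusted p = 0.600 with an estimated correlation). That call was lost without DMSO 2 (0.0710), DMSO 3 (0.105) or TPA 1 (0.248), with library size scaling (0.114) and in the GC-corrected blocked fit (0.0896).

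Few stress and glycolysis genes passed. Of 29 tested unfolded protein and ATF4 response genes 0 passed over all genes (14 at an unadjusted p under 0.05, 11 higher with DESeq2 and 1 with limma-voom), and 10 were higher adjusted over the list alone. The block called 8, among them CHAC1, a glutathione-degrading enzyme gene (2.69 ± 0.52, adjusted p = 0.0583, 0.000623 with the block, log2 3.54 without DMSO 1), and CEBPB (1.55 ± 0.36, 0.0707, 0.0105 with the block). The list's median was 0.64 (camera adjusted p = 3.1e-08, adjusted p = 0.316 with an estimated correlation and 0.0920 with fry), and 14 were higher in the GC-corrected blocked fit, with a median of 0.62. Of 29 tested glycolysis and hypoxia genes ANKRD37 rose from 3.74 ± 0.268 to 13.7 ± 0.401 CPM (1.87 ± 0.22, adjusted p = 0.0250), 0 fell and 28 did not pass, and 7 rose adjusted over the list alone. The hexokinase gene HK1 had 1.12 ± 0.22 (0.0609, 0.0235 with the block, which called 3 higher). The median was 0.62 before and 0.30 after the GC correction with block (camera adjusted p = 2.2e-06 and 0.00028, and adjusted p = 0.375 with an estimated correlation and 0.104 with fry), and the GC-corrected blocked fit called 9 higher and 1 lower. The medians of pairs 1, 2 and 3 were 0.20, 0.79 and 0.71 before the GC correction and 0.13, 0.36 and 0.37 after it.

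**Figure D4:**
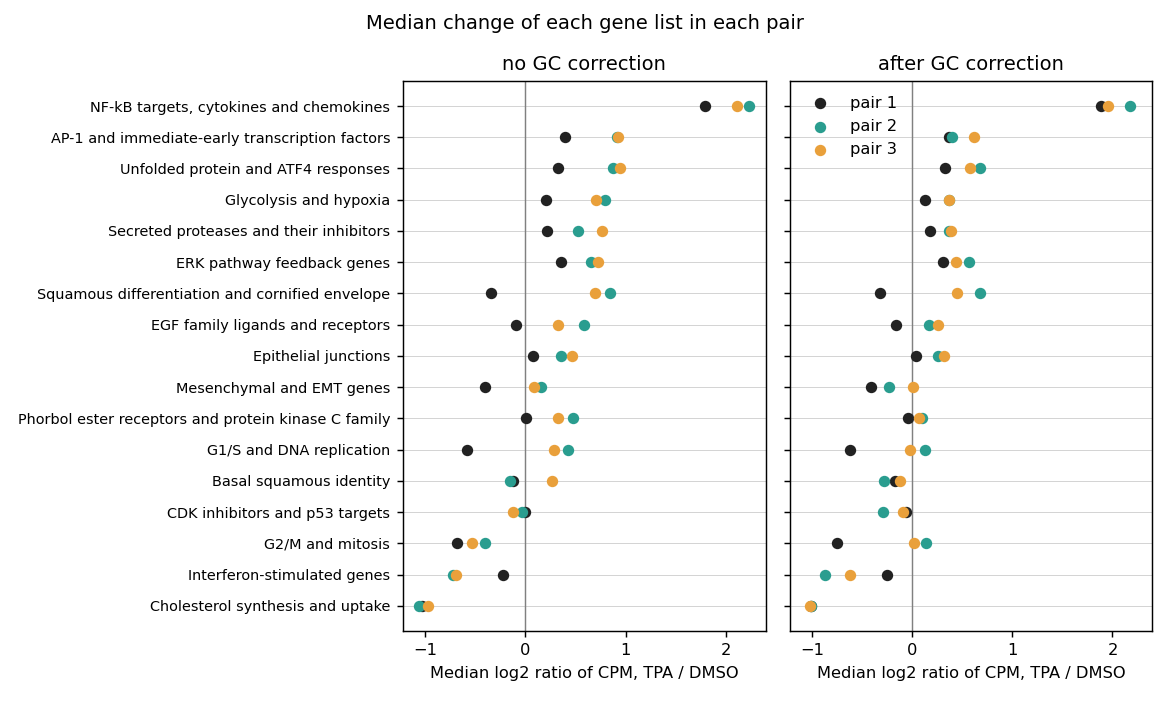
Median log2 ratio of CPM, TPA over DMSO (x axis), of the tested members of 17 gene lists (y axis) in pairs 1, 2 and 3, without (left) and with (right) removal of each library's trend on GC content. The NF-kB list lies furthest right, at 1.79 to 2.23 on the left, and the cholesterol list near -1.0 in every pair in both panels, while the G2/M list goes from -0.41 and -0.53 to 0.14 and 0.02 in pairs 2 and 3.

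Markers of other cell types and histone genes gave no call in the comparison of 3 with 3 libraries. Of 4 tested fibroblast markers, 3 leukocyte markers and 6 endothelial markers, 0 passed over all genes (edgeR), with 0, 2 and 0 at an unadjusted p under 0.05. DESeq2 called 1 leukocyte marker, CD3E, lower, as did the block and the adjustment over the list alone, and limma-voom called 0. In the GC-corrected blocked fit 2 fibroblast markers, 1 leukocyte marker and 0 endothelial markers were lower, 0 were higher, and the medians were -0.96, -0.35 and -0.67. Adjusted over the list alone 0 fibroblast, 0 endothelial and 0 histone genes passed. The lists' median log2 fold changes were -0.43, -0.08 and -0.26, and the endothelial list had a mean of 0.06 and a camera direction of up (adjusted p = 0.751). Of 26 tested replication-dependent histone genes, whose transcripts lack a poly(A) tail, 0 passed (0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom), with medians of -0.81, 0.54 and 0.29 in pairs 1, 2 and 3 (camera adjusted p = 0.526). Without TPA 1 that list's adjusted p was 1.4e-05, and 2.73e-05 without both libraries numbered 1, where 22 of the 26 were called higher. No list member called in the comparison of 3 with 3 libraries changed direction under another scaling, but by library size alone the medians of the protein kinase C, basal, mesenchymal, G1/S and histone lists turned negative, and with RLE factors those of the CDK inhibitor and leukocyte lists turned positive.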

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

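The term for libraries numbered 1 against 2 and 3, the fits without both libraries numbered 1, the GC correction with and without the block, the genes with a GC value only and the block with an estimated correlation were chosen after the data were seen; the other alternatives were planned.

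Of 835 values of the 44 named genes under alternatives, 618 kept their direction and their side of the threshold, 148 kept the direction but no longer passed, 67 kept the direction and now passed, and 2 changed direction. Both of the last were PRKCH (-0.10 as reported), at 0.00329 without DMSO 1 and 0.024 without both libraries numbered 1. With the GC correction and no block, SERPINB13, MAFG, TOP2A, MSMO1 and HMGCS1 no longer passed, with smaller fold changes. The replicate block and the GC-corrected blocked fit kept all named calls and added 8 each.

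The counts of genes higher and lower in TPA, 188 and 86 (all at least 2-fold), stayed within 1.5 times of these with RLE and upper-quartile factors, the stricter filter and the genes with a GC value only. Under other settings they moved, and the cause was not tested except where stated. Scaling by library size alone gave 219 lower, with 124 higher and 218 lower at least 2-fold, as its factors shift all genes. No filter gave 429 and 202, all at least 2-fold, from more genes tested. DESeq2 gave 1702 and 915 (951 and 737 at least 2-fold), and limma-voom 130 lower, all at least 2-fold. The block gave 1000 and 1423 (703 and 1254), the term for libraries numbered 1 2261 and 2740 (787 and 1806), and leaving out both libraries numbered 1 7216 and 7475 (2431 and 4350), from fewer and closer libraries. The GC correction gave 680 and 618 (311 and 412), and with the block 1879 and 2127 (527 and 1063). At a threshold of 0.01 the counts were 0 and 0, with 4814 genes at an unadjusted p under 0.05, and glmTreat at 2-fold gave 5 and 0. With 1 library left out the counts ran from 0 to 5577 higher and from 0 to 6297 lower (0 to 1891 and 0 to 4419 at least 2-fold), lowest without DMSO 2 and highest without TPA 1.

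Of the 19 lists tested, 11 passed with camera. All 19 kept their direction and side of the threshold with RLE factors, upper-quartile factors, no filter, the term for libraries numbered 1 and the replicate block, which changed no list call. The largest dependence was on the correlation between genes. With an estimated correlation none of the 11 passed: adjusted p was 0.268 for AP-1, 0.195 for ERK feedback, 0.195 for proteases, 0.146 for NF-kB, 0.566 for squamous differentiation, 0.290 for junctions, 0.146 for G2/M, 0.481 for cholesterol, 0.600 for interferon, 0.316 for unfolded protein and 0.375 for glycolysis. With the block and an estimated correlation it was 0.413 for AP-1, ERK feedback, proteases, junctions, interferon and unfolded protein, 0.290 for NF-kB and cholesterol, 0.581 for squamous differentiation, 0.360 for G2/M and 0.513 for glycolysis. Fry, which tests whether a list's genes move 1 way without comparing them with other genes, gave 0.190 for squamous differentiation, 0.0920 for junctions and unfolded protein, 0.125 for cholesterol and interferon and 0.104 for glycolysis, and turned the endothelial markers down (0.920).

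With the GC correction G2/M had an adjusted p of 0.454 and interferon 0.230, and the endothelial markers and histones turned down (0.830 each). With the GC correction and the block these were 0.295, 0.0896, 0.782 and 0.750, and the basal list turned down (0.546). The G2/M median went from -0.46 to -0.18 between the reported fit and the GC-corrected blocked fit, and that of interferon from -0.58 to -0.56. Library size alone gave 0.114 for interferon. The stricter filter gave 0.0606 for squamous differentiation and 0.0705 for junctions, from fewer genes tested. Without both libraries numbered 1 the EGF list (0.0377) and histones (2.73e-05) passed, G2/M did not (0.0917), and G1/S turned up (0.0283). The cause of these changes was not tested further.

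With 1 library left out, adjusted p ran from 0.0144 to 0.921 for G1/S, which turned up without TPA 1, DMSO 2 (0.847) or DMSO 3. It ran from 0.000331 to 0.248 for interferon, from 8.59e-05 to 0.138 for G2/M, from 1.32e-08 to 0.163 for cholesterol and from 1.4e-05 to 0.814 for histones, each at its extreme without TPA 1 except at the lower end for interferon and cholesterol (without DMSO 1) and for G2/M (without TPA 2) and at the upper end for histones (without DMSO 1). Histones turned down without TPA 2 (0.347) or TPA 3 (0.585). For the endothelial markers it ran from 0.365 to 0.994, with a change of direction without TPA 2. The log2 fold change of PRKCH ran from -0.17 to 0.00329.

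Depth limits genes with few counts, since a count of 0 in a library allows up to 0.0915 to 0.109 CPM. The spread between libraries limits small changes too. In simulated counts with the spread of the unblocked fit, 2.99% of genes changed 2-fold were recovered, against 97.0% of those changed 8-fold. With the spread of the blocked fit and the same library sizes, 34.3% and 100% were recovered. DESeq2 and limma-voom give no list test of their own here, and the GC-corrected fits cover only the 21024 genes with a GC value.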

Other observations

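Of the tests in this part, those of an effect of TPA shared by all cultures, of transcript length, of RNA of TPA 1 in DMSO 1 and of a response that differs between the sets were chosen after the result was seen, as were the gene families; the other tests were chosen before.

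Of 13 tested members of the interleukin 1 family (of 19), 5 rose, 1 fell and 7 did not pass, with 8 and 1 in the blocked fit and 10 and 1 in the GC-corrected blocked fit. The agonist gene IL36G rose by log2 4.86 ± 0.57 (edgeR quasi-likelihood, adjusted p = 0.0250, higher in 3 of 3 pairs), from 0.107 ± 0.0216 to 3.21 ± 1.88 CPM. Its DMSO level lay near the 0.0915 to 0.0987 CPM that a count of 0 in a DMSO library allows, so the size of the rise is uncertain. The IL36G antagonist gene IL36RN (2.78 ± 0.34, 0.0250), the interleukin 1 receptor antagonist gene IL1RN (4.17 ± 0.32, 0.0143, from 1.05 ± 0.346 to 19.0 ± 2.47 CPM) and the decoy receptor gene IL1R2 rose as well. IL1RAP, the accessory chain of several receptors of the family, was the 1 that fell.

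Transcription factor genes of the nuclear factor I family moved apart. NFIA fell from 148 ± 39.2 to 31.2 ± 3.59 CPM (log2 -2.25 ± 0.27, edgeR adjusted p = 0.0250) and NFIB fell (-1.62 ± 0.25, 0.0402), while NFIX rose from 23.7 ± 1.30 to 69.0 ± 11.6 CPM (1.54 ± 0.22, 0.0351) and NFIC had 0.33 ± 0.30 (0.549). The directions of the first 3 were the same in all 3 pairs, under each scaling and in the GC-corrected blocked fit. FAT4, an atypical cadherin gene, fell (-1.84 ± 0.32, 0.0487), and of the 4 genes of its family the block called 3 lower, while FAT3 had 1.30 and was called higher in the GC-corrected blocked fit (adjusted p = 0.0359). The bitter taste receptor genes TAS2R3 (-2.30 ± 0.41, 0.0498) and TAS2R5 (-2.64 ± 0.39, 0.0382) fell from 2.66 ± 0.808 and 1.58 ± 0.270 CPM. The other 10 of 12 tested genes of that family did not pass, 7, 0 and 0 of the 12 were above 0 in pairs 1, 2 and 3, and the block called 3 lower. On chromosome 18 the serpin genes SERPINB2 and SERPINB13 went opposite ways. None of the 274 calls, these included, was kept without DMSO 2 or without DMSO 3.

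The fold changes of pairs 2 and 3 follow the GC content of the transcripts (Spearman 0.65 across 12004 genes), and the median GC content was 55.2% in genes called higher and 43.5% in genes called lower. Loss of long transcripts is argued against by the partial rank correlation with length given GC content, -0.0873 against 0.638 with GC content given length. The ratio of TPA 3 to TPA 2, which share a treatment, also followed GC content (-0.519), as GC-dependent recovery of fragments that varies between libraries would give. Its medians ran from 0.11 at the lowest to -0.08 at the highest GC content, against -0.92 to 0.56 in pairs 2 and 3. The mean of TPA 2 and 3 over TPA 1, also of 1 treatment, had a correlation of 0.752 and medians from -1.32 to 0.87, and the mean of DMSO 2 and 3 over DMSO 1 had 0.427 and -0.30 to 0.25, but these compare the sets, whose cultures may differ too. A candidate explanation for at least part of the trend is such a difference in library preparation or sequencing, while an effect of TPA on GC-rich genes stays open. The trend was absent from pair 1 (-0.113), but that is 1 library per group, and both libraries numbered 1 differ from the others of their group along GC content, so an effect shared by all cultures cannot be told apart from library trends that mask it there. An effect in the cultures of libraries 2 and 3 alone was not tested. Of 2346 blocked calls with a GC value, 1959 were called the same way in the GC-corrected blocked fit, 915 of 980 higher and 1044 of 1366 lower.

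The libraries numbered 1 differ from those numbered 2 and 3 in both groups, in basal genes too (KRT5 had 428 CPM in DMSO 1, 1736 in DMSO 2 and 1780 in DMSO 3). In DMSO, GC-dependent recovery alone is argued against, as far as the median GC content of a gene's annotated transcripts measures it. Of 583 genes at least 2-fold apart between DMSO 1 and the mean of DMSO 2 and 3, 402 (69.0%) stayed so after the GC correction. The TPA libraries, whose GC trend between the sets was larger (medians from -1.32 to 0.87), were not tested in this way. RNA of TPA 1 mixed into DMSO 1 is argued against as the cause of its low KRT5 level. The 6 genes with the largest rise among those with an average log2 CPM of at least 1 allow at most 1.21%, where that level needs 78.6%. A small share stays possible, and RNA of DMSO 1 in TPA 1 was not tested. A full swap to an unrelated line in 1 set is argued against by 0 protein-coding genes at 10 CPM or more in 1 set with a count of 0 in the other. A partial mix with another line, or a closely related line, could also give 0 such genes and stays open. A test of whether the response to TPA differs between the sets called 9925 of 21024 genes, and 5159 with the GC correction. Its spread comes from libraries 2 and 3 alone, which may be technical replicates, and each group has 1 library numbered 1, so a difference in response stays open. A different passage, day or state of the cultures may stand behind the sets, which the labels do not state, so culture and library batch stay open.

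With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 274 genes and the highest of the other splits 0, so 1 of the 10 splits reached the real count, and likewise 1 for genes changed at least 2-fold (274 against 0). For gene lists, 2 of the 10 splits reached the real count of 11, the other being DMSO 1, TPA 2 and TPA 3 against the rest, also 11. Each other split called at least 5 lists, so passing camera at the preset correlation does not by itself set the TPA grouping apart. The 3 other splits that part all pairs called 0 genes with the block, against 2423 for the real one. Each of these 3 swaps the TPA and DMSO libraries of 1 pair, so any difference shared by the pairs adds to their spread. Few calls were therefore likely in advance, and so few splits allow no share under 0.05. These splits also rest on pairs 2 and 3, which the correlations do not tell apart.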
